A study of Escherichia coli str. K-12 substr. MG1655 with 12 samples.

How the data were processed

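Escherichia coli K-12 MG1655 was grown in minimal medium with glucose at 30 °C to mid-exponential phase, per the labels' protocols. Rifampicin, an antibiotic that binds RNA polymerase (RNAP) and stops transcription before elongation, was given at 150 μg/mL for 30 min to some cultures. The labels give it for RNAP with rifampicin and its mock, and not for σ70. The 12 samples form 6 groups of 2. 3 groups are ChIP-exo immunoprecipitations, of σ70, of RNAP with rifampicin and of RNAP without it, and the other 3 are their IgG mocks. In ChIP-exo, a 5′ to 3′ exonuclease trims the crosslinked DNA, so that the 5′ end of a read marks where the enzyme stopped beside the bound complex.

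The values are per-base tracks that the authors deposited, 1 for each immunoprecipitation, in a unit of score. As read from the deposited files and their values, a score is the number of read 5′ ends at a base of 1 strand less a scaled mock, and minus-strand values carry a negative sign, which was removed here. Bases at or below 0 after the subtraction are not listed. The most common score was 1 in the σ70 and rifampicin tracks and 0.6 in the track without rifampicin, so the counts behind the latter were scaled before deposit. Per the file contents, the deposited smoothed σ70 track holds signal on the plus strand, with no value under 0.5, and served as an alternative here. CASAVA 1.4 is named in the submitters' processing notes. The aligner, the treatment of reads that map to several places and the scaling factor of the mock are not given in the sources used here. The mocks were not analysed here as tracks of their own.

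Each track merges its 2 replicates. No replicate spread, no test between groups and no p-value could be had. Depth in reads is also unknown, since the scores are subtracted and scaled. The errors given are bootstrap values with 1000 draws: over 20-bp blocks within a region (SE of a log2 ratio), over genes, gaps or sites (95% interval of a median), over 10-kb blocks (shares) and over 100-kb pieces of the chromosome (lags). They cover unevenness along the chromosome and not variation between cultures.

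The tracks name the MG1655 chromosome without a version and end at base 4639680. The gene table used for names belongs to assembly ASM584v2, has no strand and extends past that base. No genome sequence was used here. The tracks' signal was correlated with the space between genes at shifts of −500 to 3000 bp in steps of 4 bp. Over the first 250 kb the best shift was 0 bp (r = 0.319, and at most 0.133 more than 150 bp away), and its 5 windows of 50 kb gave −36 to 4 bp. In the rest, 76 of 87 windows had a clear best shift, all between 724 and 2104 bp. Coordinates were not converted. Gene names were used only in the first 250 kb, which hold 240 of the 4651 genes in the table and 5.39% of the track length, and no table coordinate is printed. Results over the whole chromosome use the tracks' own coordinates. The end of this stretch was chosen after the data were examined.

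Scores were scaled to a sum of 1000000 per track and summed over both strands. Densities are in scaled signal per kb, and log2 ratios were taken after a pseudocount of 4 was added. A gene interior is a gene of at least 600 bp without 200 bp at each end, and a gap is a space of at least 100 bp between neighbouring genes. Regions whose mean density over the tracks compared was under 20 were left out, which kept 148 of 159 interiors and 82 of 85 gaps. The planned promoter windows, gene bodies measured from the gene start and predicted promoters needed strand or sequence and were replaced by gaps, by interiors and by lags between tracks. An enriched bin is a 100-bp bin of at least 5 times the median of the bins with signal, and a domain is a run of enriched bins of at least 1 kb. σ70 sites are runs of enriched σ70 bins. A site is isolated when no other centre lies within 500 bp, and its site-to-flank ratio compares 150 bp on each side of the centre with the flanks from 200 to 1000 bp. A first look at sites chosen on the RNAP track with rifampicin was set aside because that choice favours the track it is made on. Lags are cross-correlations of log2(1 + score) on the same strand, smoothed over 3 bp, less the mean over 401 bp, with scores limited at percentile 99.5. The mean lag weights the lags within 80 bp by the positive part of the correlation, leaving out those within 2 bp of 0, where all pairs of tracks shared a sharp peak. The lag measures, the classes of sites by strength and location, and regions moved by 30 bp were added after the data were examined. The other alternatives were fixed before: scaling to the background of 1-kb bins, a limit on single bases, other filters, pseudocounts, gap lengths, interior lengths, thresholds and bins, single strands and the smoothed track. The background is the median signal of the 1-kb bins that rank below the median bin. In the named stretch 90.08% of 100-bp bins lay in genes, so this background can itself hold signal from genes.

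The gene lists and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 10 most positive and the 10 most negative regions among those with a mean signal above the median, and up to 3 members of each list with the highest mean signal. Where a list is described, further members beyond this rule are named too, without a remark. Other genes are named with the remark that they were chosen after their values were seen. rRNA and tRNA genes share reads with near-identical copies, and their values are uncertain. A list's median was placed among 10000 random lists of the same size matched on mean signal where at least 3 members were measured.

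The log2 ratio step was tested on simulated interior totals for the comparison of RNAP without and with rifampicin over 148 interiors. Scaling to the track total, mock subtraction and the bootstrap SE were not part of this simulation, so it does not test them. Of 20 interiors changed 4-fold, 100% came out above 0, with a median log2 of 1.95. Of 20 changed 2-fold, 80% did, with a median of 1.07, and the 108 unchanged interiors had a median of −0.04. A simulated lag of 30 bp was recovered as 30 bp on both strands, and a shift of −400 bp of the gene table as −416 bp. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.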

Results

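ChIP-exo tracks of σ70, the housekeeping sigma factor, and of RNAP with and without rifampicin were compared in exponentially growing E. coli K-12 MG1655. Each of the 3 tracks merged 2 replicates, so none of the differences has a replicate check. The scores summed to 2452406 for σ70, 2106841 for RNAP with rifampicin and 2048771 for RNAP without it. The most common score was 1 with rifampicin and 0.6 without it, so similar sums need not mean similar depth in reads. The RNAP signal was more concentrated with rifampicin: the top 1% of 100-bp bins held 47.3% of it, against 30.8% without rifampicin and 32.3% for σ70. Of 46396 bins, 3731 had no signal in the track with rifampicin, 399 in that without and 60 in the σ70 track. The track with rifampicin listed 5.42% of plus-strand and 5.52% of minus-strand bases, against 10.6% and 10.7% without it. Whether the drug or the libraries themselves gave the higher concentration was not tested.

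The first comparison asked where RNAP lay when transcription ran and when rifampicin held it back. Without rifampicin, more of the RNAP signal lay inside genes. Over the 148 gene interiors measured in the first 250 kb, the median log2 ratio without over with rifampicin was 1.44 (95% interval 1.11 to 1.75), or 2.72-fold. The ratio was above 0 in 128 interiors (86.5%), in 105 of them by more than 2 bootstrap SE, and it was below 0 by as much in 6. Among interiors with a mean signal above the median and apart from rRNA genes, the highest ratios were those of leuB, an enzyme of leucine synthesis, at 4.21 ± 0.27 (bootstrap SE), dpaA at 4.11 ± 0.32, lpxC, the deacetylase that commits precursors to lipid A, at 4.06 ± 0.48, and surA, a periplasmic chaperone of outer membrane proteins, at 4.06 ± 0.27. They were followed by aceF and lpd, subunits of pyruvate dehydrogenase, at 3.56 ± 0.38 and 3.52 ± 0.19, mltD, a murein transglycosylase, at 3.54 ± 0.21, and acnB, an aconitase, at 3.43 ± 0.21. Some values depended on the region taken. Over whole genes lpxC stood at 1.80 ± 0.74 and dpaA at 2.56 ± 0.35, while leuB and surA stood at 3.99 ± 0.21 and 3.98 ± 0.25. Under the same limit on signal, the lowest were those of nhaA, a sodium-proton antiporter, at −1.94 ± 0.35, sfsA at −1.53 ± 0.27, gloB, a glyoxalase, at −1.36 ± 0.41, yadC at −1.33 ± 0.27 and yabP at −0.75 ± 0.37. The next under that limit, leuO, yafV, ampE, yafC and bamA, ran from −0.42 to 0.07, each within 2 SE of 0. These ratios depend on scaling each track to its total. Scaling to the background of 1-kb bins lowered every log2 ratio by up to 0.93, with the median of interiors at 0.62 and 97 of 150 interiors (64.7%) above 0. Under that scaling 72 interiors were above 0 by more than 2 SE and 28 below it by as much. Its background can hold signal from genes, so it may remove part of a change inside them.

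All 12 measured interiors of the amino acid biosynthesis list had more RNAP signal without rifampicin, under both scalings. Their ratios ran from 1.64 for carA to 4.21 for leuB, with a median of 2.31, which lay at percentile 98.2 of random lists matched on signal (95% of those between 0.74 and 2.26). The members came from few operons and were not independent: the leucine genes leuA, leuC and leuD stood at 3.00 ± 0.19, 2.55 ± 0.34 and 2.86 ± 0.62, and the threonine genes thrA, thrB and thrC at 2.25 ± 0.18, 1.74 ± 0.26 and 2.59 ± 0.21. The remaining member in the stretch, ilvH, was too short for an interior, and over the whole gene its ratio was lower, at 0.58 ± 0.31, and −0.32 with background scaling. Of the σE list, which serves envelope stress, 3 of 4 interiors were above 0. Its median of 0.91 lay at percentile 34.4 of random lists, and its members parted. The genes surA and lpxD stood at 4.06 and 1.75 ± 0.24, against bamA at 0.07 ± 0.36 and the protease gene degP at −0.06 ± 0.34. The value of degP depended on the region taken, at 1.24 with interiors from 400 bp and −1.15 ± 0.35 over the whole gene. The short gene skp stood at 1.62 ± 0.34 over its whole length. With background scaling bamA fell below 0, and 2 of the 4 were above it.

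Lists with fewer than 3 measured interiors gave values only. In the tricarboxylic acid cycle list these were lpd and acnB, above. The heat-shock genes dnaK and dnaJ, of the σ32 list, stood at 2.78 ± 0.19 and 0.45 ± 0.54, and dnaJ was below 0 with background scaling. The ribosomal protein gene rpsB stood at 2.97 ± 0.21, the iron uptake genes fhuA and fhuC at 1.55 ± 0.17 and 2.56 ± 0.54, and araB, for arabinose use, at 1.09 ± 0.30. The fhuC interior had an RNAP density of only 5.96 per kb with rifampicin, near the pseudocount of 4, so its ratio is uncertain. Over whole genes araA and araD, whose interiors had too little signal, stood at 0.73 ± 0.20 and 0.42 ± 0.36, and at −0.06 and −0.32 with background scaling. For other genes too short to have an interior, whole-gene ratios were 5.05 ± 0.20 for leuL and 2.96 ± 0.88 for thrL, which encode leader peptides, 1.82 ± 0.30 for rpsT, and −0.17 ± 0.29 for the small RNA sgrS. The 4 tRNA genes ranged from 3.85 ± 1.38 for aspV to 5.40 ± 0.80 for aspU. No gene of the lists for RNAP and sigma factors, ATP synthase, σ54, σ28 and chemotaxis, σS, cold shock, glycolysis, or outer membrane and cell envelope lay in this stretch.

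The longest stretch of RNAP signal in named genes was an rRNA operon, whose reads are shared with near-identical copies. The interiors of rrsH and rrlH, for the small- and large-subunit rRNA, had log2 ratios of 3.77 ± 0.44 and 4.01 ± 0.20, and the whole of rrfH, for the smallest rRNA, had an RNAP density of 428 per kb without rifampicin and 1.03 with it. The latter lay below the pseudocount, so no ratio is given. The former pair had RNAP densities of 2122 and 1331 per kb without rifampicin. A run of enriched bins at 223401 to 228200 covered rrsH, the tRNA genes ileV and alaV, and 84.1% of rrlH. Over the whole chromosome, 44 such domains of at least 1 kb were found without rifampicin, holding 16.6% of the signal, against 14 with rifampicin (3.30% of the signal) and 4 for σ70 (1.49%). The longest were 4900 bp (4033101 to 4038000), 4800 bp (the rrsH to rrlH run), 4700 bp (4205801 to 4210500) and 4400 bp (4164301 to 4168700) without rifampicin, and 1200 bp with it. In the 4900-bp domain the RNAP density was 1942 per kb without rifampicin and 296 with it. The counts depended on the settings, with 8 domains without rifampicin and 1 with it at a threshold of 10 times the median bin.

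In the gaps between genes the RNAP tracks, scaled to their totals, did not differ in 1 direction. Without strand, gaps that hold promoters were not told apart from gaps after genes or inside operons, so these values do not describe promoters alone. The median log2 ratio over 82 gaps was −0.26 (−0.66 to 0.42), with 38 gaps above 0 and 44 below, and 28 on each side by more than 2 SE. With background scaling the median was −1.17 (−1.57 to −0.50), with 27 gaps (32.9%) above 0 against 46.3% before. Under that scaling 13 gaps were above 0 by more than 2 SE and 43 below it by as much. Among gaps with a mean signal above the median, the lowest ratios were −4.54 ± 0.43 for the gap between kefC and folA, the latter for dihydrofolate reductase, −3.99 ± 0.75 for fadE/gmhA, −3.45 ± 0.67 for acnB/yacL, −3.31 ± 0.31 for dinJ/yafL and −3.26 ± 0.50 for yafC/yafD. The gaps dgt/degP, yaeP/yaeQ, yaaI/dnaK, hemL/yadX and gcd/hpt followed, from −2.91 to −2.19. Under the same limit the highest were alaV/rrlH, inside the rRNA operon, at 4.29 ± 0.43, lspA/fkpB at 4.20 ± 0.33 and rpsB/tsf at 3.93 ± 0.58. Next under that limit came yabR/ilvI at 1.98 ± 0.57 and leuL/leuO at 1.54 ± 0.17, then gmhB/rrsH, rpsT/yaaY, dpaA/yafQ and insA1/rpsT, from 1.27 to 1.10, and lpxC/secM at 0.49 ± 0.60, which was below 0 with background scaling. Of the gaps with less signal, pdhR/aceE, beside the first gene of pyruvate dehydrogenase, had an RNAP density of 301 per kb without rifampicin and 2.97 with it, the latter below the pseudocount. It was chosen after its values were seen.

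**Figure D1:**
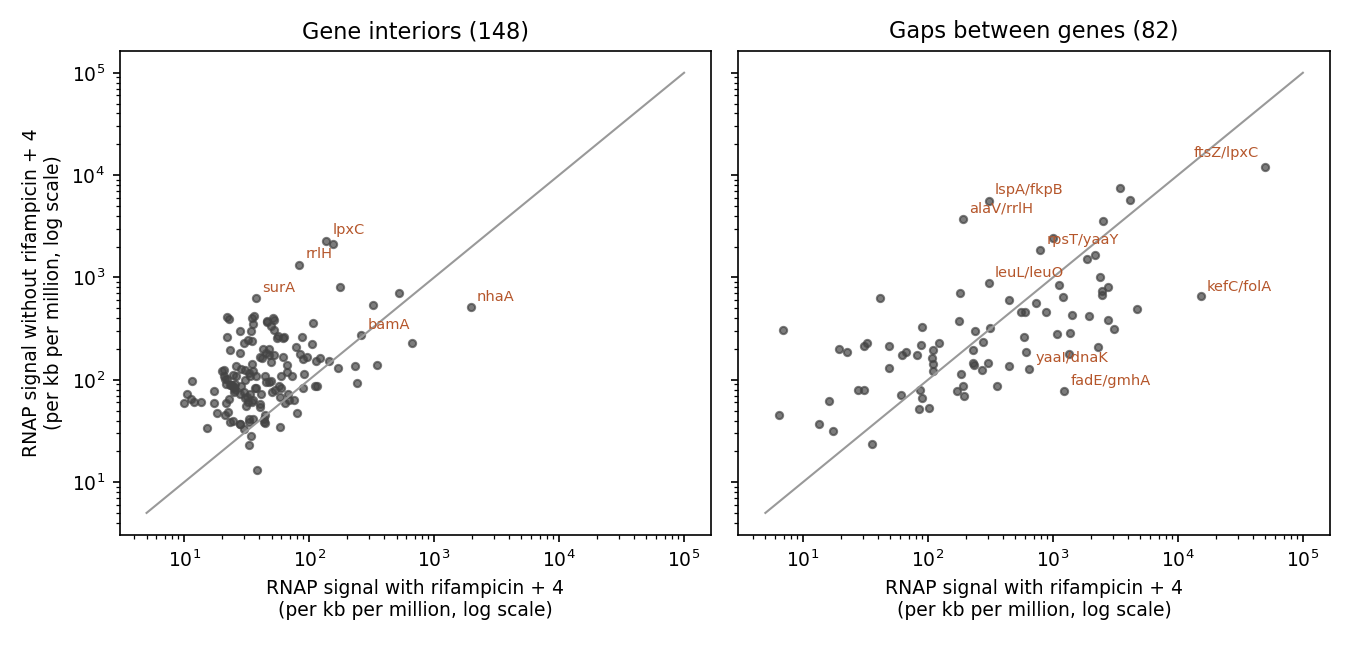
RNAP signal in 148 gene interiors (left) and 82 gaps between genes (right), with rifampicin on the x axis and without it on the y axis, in scaled signal per kb plus the pseudocount of 4, both on log scales. Each point is 1 region and the line marks equal values. 128 of the 148 interiors lie above the line, and 97 of 150 do with background scaling.

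Set against the genes beside them, gaps stood out more with rifampicin. The median log2 ratio of a gap to its flanking interiors, over 78 gaps, was 2.63 (1.42 to 3.20) with rifampicin, 0.88 (0.48 to 1.42) without it and 1.43 (0.62 to 2.21) for σ70. The paired difference, without minus with rifampicin, was −1.43 (−1.99 to −0.83). This contrast does not depend on how the tracks are scaled to each other, apart from the pseudocount. The gaps made up 7.37% of the stretch and held 44.2% (29.5 to 58.4) of its RNAP signal with rifampicin, 17.7% (12.8 to 22.7) without it and 28.04% (19.9 to 35.2) of its σ70 signal.

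The second comparison asked whether σ70 and rifampicin-held RNAP lay at the same places. The σ70 track came from cultures without rifampicin, so this pair of tracks differs in the drug as well as the antibody. Across 83 gaps, log2 densities of σ70 and RNAP with rifampicin had a Pearson correlation of 0.71 (0.57 to 0.81) and a Spearman correlation of 0.67. Gaps are not independent replicates. Over all 46396 bins of the chromosome, log2 scores of σ70 had a Pearson correlation of 0.69 with RNAP with rifampicin and 0.77 with RNAP without it. The correlation with σ70 was therefore not particular to the track with rifampicin. The gap between ftsZ, the cell division gene, and lpxC had the highest density in all 3 tracks. Its densities were 23975 per kb for σ70, 49655 for RNAP with rifampicin and 11979 without it. This gap was chosen after its values were seen. Its log2 ratio of σ70 over RNAP with rifampicin, −1.05 ± 1.08, lay within 2 SE of 0. On single strands that ratio went both ways, at −1.08 on the plus and 1.32 on the minus strand. A gap counted as bound at 5 or more times the median interior of the same track. Of 85 gaps, 52 were bound by RNAP with rifampicin, 33 by σ70 and 23 by RNAP without rifampicin. Interiors were denser without rifampicin, so the cut-off differed between the RNAP tracks. The counts 52 and 23 therefore do not compare gap densities. σ70 and RNAP with rifampicin shared 29, where independent lists would share 20.2. Over the chromosome, 3493 bins were enriched for σ70, 7061 for RNAP with rifampicin and 5784 without it. σ70 shared 2420 with RNAP with rifampicin and 2564 with RNAP without it, against 532 and 435 for independent lists.

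Some gaps with a mean signal above the median parted the pair. Since σ70 was taken without rifampicin, effects of the drug and of the antibody cannot be told apart in these ratios. They share their denominator with the ratios of RNAP without over with rifampicin, and several gaps named here were also named there. σ70 was higher relative to RNAP with rifampicin at speE/yacC (log2 4.01 ± 0.61), panD/rpnC (3.83 ± 0.31), dapB/carA (3.79 ± 0.40), beside the carbamoyl phosphate synthetase gene carA, and rpsT/yaaY (3.02 ± 0.27). The gaps yabR/ilvI, leuL/leuO, gmhB/rrsH, alaV/rrlH, dnaQ/aspV and yacM/guaC ran from 2.41 to 1.41, and yacM/guaC turned to −0.11 with background scaling, which lowered these ratios by up to 1.51. RNAP was higher at kefC/folA (−4.36 ± 0.77), acnB/yacL (−4.13 ± 1.11), dgt/degP (−3.90 ± 0.66), yafC/yafD (−2.87 ± 0.46) and yaeP/yaeQ (−2.86 ± 0.80). The gaps dinJ/yafL, fadE/gmhA, hemL/yadX, talB/mog and lptD/djlA followed, from −2.51 to −1.70. On the plus strand alone, kefC/folA and yaeP/yaeQ turned to 0.44 and 0.26. The gap lptD/djlA, within 2 SE of 0 at −1.70 ± 0.98, stood at 0.95 on the minus strand and at 0.48 with regions moved 30 bp left.

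At the 1414 isolated σ70 sites of the chromosome, both RNAP tracks were above their flanks. The median log2 site-to-flank ratio was 1.78 (1.70 to 1.84) for σ70, 1.34 (1.21 to 1.48) for RNAP with rifampicin and 1.54 (1.45 to 1.65) without it. The difference without minus with rifampicin was small, at 0.10 (0.0013 to 0.22), and turned to −0.19 (−0.37 to 0.0026) for sites chosen at 10 times the median bin. It went both ways by strength: −0.91 (−1.32 to −0.63) at the strongest 200 sites and 0.57 (0.31 to 0.76) at the weakest 400. At the strongest 200, median RNAP density at the site was 1181 per kb with rifampicin and 1506 without it. In their flanks it was 109 and 257, so the lower ratio did not mean less RNAP signal at these sites. In the named stretch the site-to-flank difference was −1.70 (−2.59 to −0.75) at 22 sites in gaps and 0.64 (−0.06 to 1.11) at 52 sites in genes. Gaps and genes thus differed by −2.34 (−3.34 to −1.05). Among sites of shared strength, 11 in gaps and 25 in genes, they differed by −2.86 (−5.27 to −1.09). At the 22 sites in gaps, median site density was itself lower without rifampicin, at 433 per kb against 868.

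**Figure D2:**
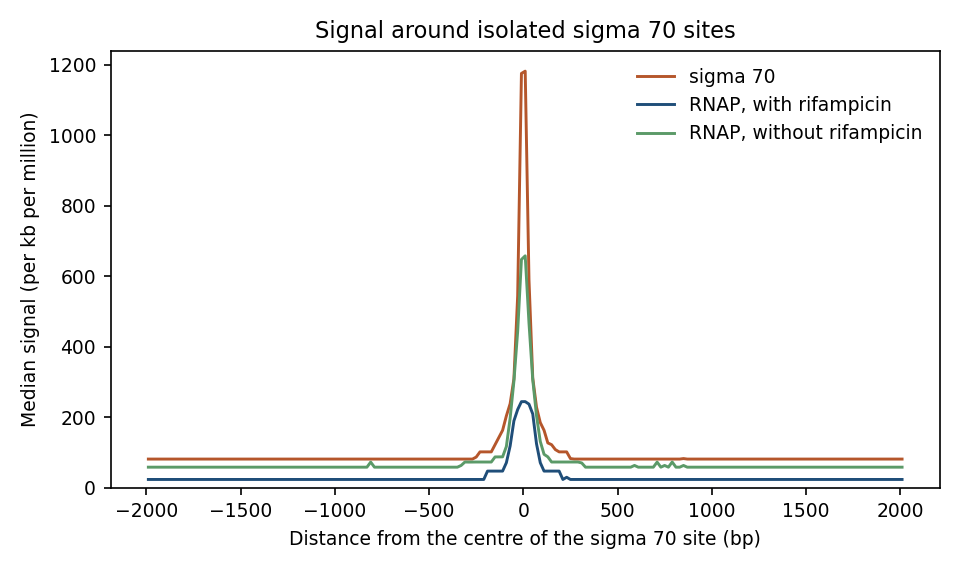
Median signal around the 1414 isolated σ70 sites, in scaled signal per kb, against the distance from the site centre in bp, for the 3 tracks (lines). All 3 peak at the centre. Sites were chosen on the σ70 track, a choice that favours that track, and the median log2 site-to-flank ratios are 1.78 for σ70, 1.34 for RNAP with rifampicin and 1.54 without it.

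The third comparison asked where the exonuclease stopped in each track. σ70 read ends lay on average 3′ of RNAP read ends on the same strand. Against RNAP with rifampicin the mean lag was 26.5 bp (25.3 to 27.7) on the plus strand and 27.9 bp (26.4 to 29.3) on the minus strand, positive in 46 of 46 pieces of 100 kb. Against RNAP without rifampicin it was 25.6 bp (24.7 to 26.6) and 25.8 bp (24.8 to 26.6). Read ends of RNAP without rifampicin lay 8.07 bp (7.26 to 8.77) and 8.61 bp (7.93 to 9.30) 3′ of those with it, but this curve was nearly symmetric: the correlation at the plus-strand mean lag was 0.27, and 0.23 at the same distance in the other direction, against 0.19 and 0.04 for σ70 and RNAP with rifampicin. The lag of highest correlation for σ70, among those more than 10 and up to 80 bp from 0, was 30 bp (25 to 32) and 29 bp (26 to 34) against RNAP with rifampicin, and 21 bp (20 to 25) and 23 bp (14 to 23) against RNAP without it. All pairs also shared a sharp peak at lag 0, with correlations of 0.25 to 0.44, which was left out of the mean. Within a track, plus-strand ends correlated most with minus-strand ends at a distance of 67 bp (66 to 68) for σ70. For RNAP this distance was 52 bp (40 to 61) with rifampicin and 40 bp (40 to 40) without it. The 3 correlations were only 0.086, 0.045 and 0.034. Subtracting the local mean can push long distances below 0, so these values do not give the most common distance between ends. The RNAP values lay on narrow peaks at 40 and 52 bp that all 3 tracks showed.

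**Figure D3:**
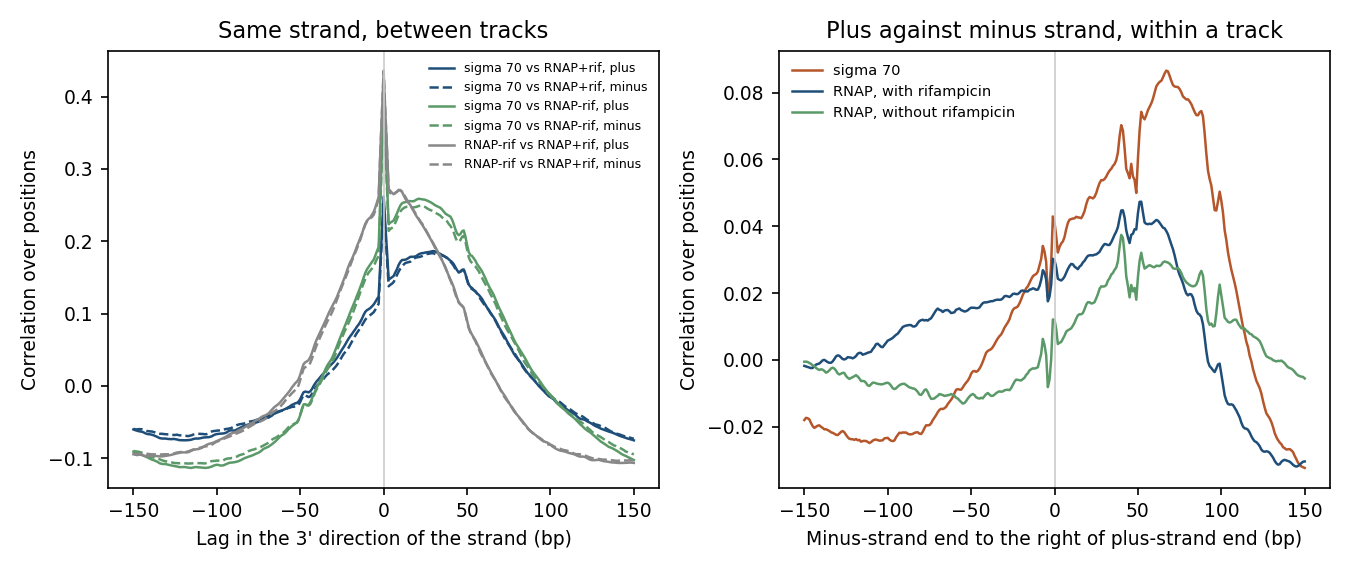
Left, correlation of read ends on the same strand between tracks, against the lag in bp in the 3′ direction, with plus strands as full and minus strands as dashed lines. Right, correlation of plus-strand with minus-strand ends within each track, against their distance in bp. Away from the peak at 0, the curves of σ70 against RNAP with rifampicin lie to the right of 0, with mean lags of 26.5 and 27.9 bp.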

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

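Values counted as changed when they left their bootstrap interval, or for counts moved by over 1.5 times. Of 90 alternative values of the main results, 81 stayed, 8 moved and 1, whose interval had excluded 0, changed sign. The gap median of −0.26, whose interval spanned 0, stayed within it but turned to 0.06 with gaps of at least 50 bp and to 0.02 on the minus strand alone. The moved lag on the minus strand, the lag in shared bins and the regions moved by 30 bp were chosen after the data were examined. Scaling to the background put the median log2 ratio without over with rifampicin at 0.62 in gene interiors and −1.17 in gaps, since it lowered these ratios by up to 0.93. In interiors it was 2.02 with a filter 4 times stricter and 1.78 with interiors from 400 bp. Enriched bins with rifampicin numbered 4067 at a threshold of 10 and 12063 with 50-bp bins. The site-to-flank difference turned to −0.19 at a threshold of 10, and the cause was not tested, though the strongest sites also lay below 0. The lag of 26.5 bp became 27.9 bp on the minus strand and 24.6 bp in shared bins. The gap-to-gene difference kept its sign in all 10 alternatives (−1.66 to −1.18), as did the correlation of σ70 with RNAP over gaps in 12 (0.58 to 0.73). Of 676 alternative values of named regions, 556 stayed and 117 moved, 61 of these under background scaling. Of 13 sign changes, 10 were of values within 2 SE of 0 (bamA, dnaJ, degP, yafC, yafV, ampE, lpxC/secM and, for σ70, lptD/djlA). The other 3, all for σ70 over RNAP with rifampicin, were of values further from 0: yacM/guaC to −0.11 with background scaling, and kefC/folA to 0.44 and yaeP/yaeQ to 0.26 on the plus strand alone. Beyond the strand itself, the cause was not tested. Of 155 other values, 109 stayed and 46 moved.

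No paired analysis was possible because each track merges its 2 replicates. For the same reason no replicate was left out. TMM and DESeq2 were not run, as the scores are not counts. The total without rRNA operons, the shorter promoter window, divergent genes only and all settings for predicted promoters were not run, as they need strand, sequence or positions of genes beyond the named stretch. What depth limits was not tested, as depth in reads is unknown; 8.04% of bins had no signal with rifampicin and 0.86% without it.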

Other observations

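All tests in this part were chosen after the data were examined, that of lags in shared bins before its own result was seen and the others after.

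Several of the strongest RNAP sites with rifampicin had far less σ70 signal than RNAP signal, each as a part of its own track. RNAP signal without rifampicin was also far lower at these sites. The σ70 track too came from cultures without rifampicin, so effects of the drug and of the antibody cannot be told apart here. At 1297201 to 1297800 the track with rifampicin held 18140 of its scaled total of 1000000, against 317 for σ70 and 1135 without rifampicin. At 2226701 to 2227200 the values were 12810, 303 and 1106, and at 1553901 to 1554800 they were 12041, 404 and 734. The strongest site, 4422601 to 4423100, held 18940 with rifampicin, 10966 for σ70 and 3941 without rifampicin. At 3809401 to 3810200 the σ70 signal was the higher one, with 11091 for σ70 and 311 for RNAP with rifampicin. These sites were chosen after their values were seen. No gene was named at them, as they lie beyond the named stretch.

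A single minus-strand base of the σ70 track, 295626, carried a score of 100669, which was 4.10% of the track and 53.9 times the next highest base. If it were a strongly bound site, RNAP would be raised nearby, but RNAP signal with rifampicin within 100 bp was 1.53 times the median bin, which argues against that. The 10 neighbouring bases of the strand held 0.0698% of the signal of the base, which is consistent with 1 amplified or misaligned fragment. Which of these it was stays open.

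σ70 read ends lay 3′ of RNAP read ends on both strands. An offset between the files would move both strands the same way along the chromosome, but that shared shift was −0.70 bp, and a wrong read length for minus-strand ends would leave the plus strand at 0, where the mean lag was 26.5 bp. In the 2420 bins enriched in both tracks the lag was still 24.6 bp (22.8 to 26.4), and 26.7 bp on the minus strand, which argues against different sites as the whole cause. An RNAP footprint that encloses the σ70 footprint at the same sites stays open, as a test by the distance between paired RNAP ends was void (subtracting the local mean can push long distances below 0), and so do edges that differ between strands or sites, which were not tested.

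RNAP signal in gene interiors was higher without rifampicin. A uniform background added without rifampicin, large enough to account for the whole median change, would give a narrow spread of densities. The SD of log2 density over interiors was higher by 0.60 (0.38 to 0.87) than with such a constant added (1.24 against 0.63), which argues against that. This interval does not cover variation between cultures. Mock subtraction base by base, and a smaller background together with a change of scaling, were not modelled and stay open. As a hypothesis, elongating RNAP that rifampicin removed may account for the spread. Ratios of neighbouring interiors correlated at 0.17. The middle 95% of 10000 shuffled orders ran from −0.17 to 0.15. The observed correlation lay only just above this range, which is weak support. A scaling factor taken from a track rich in gap signal stays open as a source of part or all of the median change, which was 0.62 with background scaling. Background scaling cannot decide this, since its background can itself hold signal from genes.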
